A study of Sus scrofa with 9 samples.

How the data were processed

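The series measured polyadenylated RNA in pig MII oocytes of 3 groups, control, heat stress and heat stress plus L-Asp, with 3 libraries each. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, full-length cDNA was primed with a modified oligo(dT) primer, amplified by PCR, fragmented and sequenced in paired-end mode on an Illumina NovaSeq instrument. This preparation does not mark the strand of the RNA, and no molecular identifiers are described, so counts are not independent molecules.

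One table of the whole series was used. Per the file headers it holds, for each of 23507 genes, counts and FPKM values per library with gene coordinates, symbols and gene ontology (GO) and KEGG terms. The deposited counts were whole numbers that summed to 41693395 to 58361475 per library, and were used as deposited. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, without their roles. The genome build and the way counts were made are not given in the sources used here. The deposited FPKM values, computed by the authors, served to check the unit of the counts and to derive each gene's transcript length from the ratio of counts to FPKM. The table holds 6 further columns of per-sample values that were not used. Symbols came from the table for 13893 genes and from a table of gene names for 116, and 9498 genes have none. Coordinates are those of the table.

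Pairs of libraries were compared by the squared difference of their scaled counts, divided by the value that independent counts would give (index of dispersion). Genes needed at least 40 counts summed over the pair, and the abundance classes of this index refer to the same sum. The control pairs lay near the level that fragments of 4 counts would give, in both abundance classes, whereas the lowest pair within the other groups lay at 43.8 among genes with 100 to 300 counts, where the highest control pair lay at 4.82. The analysis planned before the data were examined used all 9 libraries. Because the control libraries differed by little more than sampling noise, their rounded mean count was used as 1 library, and the planned fit of 9 libraries is given beside each count of genes as an alternative. That change was made after the libraries had been compared, and the numbers of genes that both fits call had also been seen by then. Tests, gene lists and the rule for named genes were otherwise used as planned. Camera over GO and KEGG terms, the filter recomputed on 7 libraries and the fit of 9 libraries as an alternative were added after seeing the data.

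Genes were filtered by filterByExpr of edgeR on the 9 libraries (15012 genes kept), scaled by trimmed mean of M values (TMM) and tested with edgeR's quasi-likelihood F test (glmQLFit with robust = TRUE, glmQLFTest) in a model with 1 mean per group. The model left 4 residual degrees of freedom. An adjusted p (Benjamini-Hochberg) under 0.05 counted as a call. Recomputing the filter on the 7 libraries would keep 17876 genes and is given as an alternative, and the choice between the filters was made with both results known. CPM values are counts scaled to a common library total by TMM, and for the control they come from the averaged library with no SD.

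Of 34 gene lists, 33 had at least 5 tested genes. Each was tested per comparison with camera (limma) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. The lists covered heat shock and chaperones, chaperonins, the unfolded protein response, antioxidants, mitochondrially encoded genes, the nuclear respiratory chain, mitochondrial dynamics, aspartate use, nucleotide synthesis, glycolysis, the tricarboxylic acid cycle, lipids, apoptosis, autophagy and the proteasome. Others covered the spindle checkpoint, spindle microtubules, the actin cortex, cohesin, meiotic arrest and resumption, maternal mRNA control, oocyte genes, markers of cumulus and granulosa, theca and stroma, blood and immune and endothelial cells, DNA repair, cytosolic and mitochondrial ribosomes, translation factors, secretory traffic, DNA methylation and chromatin, inflammation and stress kinases, and splicing. Enrichment of terms of 10 to 500 genes in the called genes was planned with a hypergeometric test and had no calls to run on.

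Genes were named by a fixed rule. First came the 10 highest and 10 lowest fold changes among called genes without overlap and with at least 10 CPM. Then came up to 4 called members of each list, or 2 of smallest p as values only. Where fewer than 5 genes qualified in a direction, the 5 of smallest unadjusted p with a symbol and at least 10 CPM were given as values only. Up to 10 genes called in opposite directions for heat and for L-Asp completed the rule. The text names fewer, in that order, and some genes that the rule gives are not reported here. Of 70 genes taken from the rule for the text, 15 overlap another gene in the table, 10 of them one on the opposite strand, among these BTG4, COX6C, EEF1B2, MDH2, ND6, PAIP2, PLK1, RPS3A and SDHD. ALDOA, ATP6, ND4, PHB2, RPS3A, SDHD and SLC25A44 overlap a gene on the same strand. Their counts can hold reads of the partner, since the counting is not stated to use strand.

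The computations were tested on simulated counts drawn from the real means, dispersions and library sizes of 15012 genes, with 200 genes changed per run over 5 runs. For heat stress against control the edgeR fit of 7 libraries recovered 1.6% of genes changed 2-fold, 29.2% at 4-fold, 46% at 8-fold and 48.4% at 16-fold. For heat stress plus L-Asp against heat stress the shares were 11.6%, 47.6%, 59.6% and 56.8%, and for heat stress plus L-Asp against control 2%, 30.4%, 43.2% and 52.8%. Of all simulated calls, 38 of 351, 66 of 505 and 42 of 363 were false in the 3 comparisons. Genes were simulated independently of each other, so the simulations give no error rate for calls of gene lists.

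Alternatives were other size factors (RLE), scaling without mitochondrially encoded and the 10 most abundant genes, no filter, a mean count of at least 50, DESeq2 with its own size factors and independent filtering (22184 genes tested, without filterByExpr), the replicate number as a block, each library left out in turn, only the groups compared, and a log2 fold change of at least 1. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.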

Results

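Polyadenylated RNA was sequenced from pig (Sus scrofa) oocytes at metaphase II (MII), the stage at which a mature egg is arrested before fertilisation. Oligo(dT) priming captures RNA with a poly(A) tail. A change in tails and a change in RNA amount can therefore not be told apart in these data. The oocytes were taken with their surrounding cumulus cells and matured in culture. Control oocytes stayed at 38.5 °C. Heat stress meant culture of germinal vesicle stage oocytes at 41.5 °C for 24 h, followed by 38.5 °C until MII. A further group received L-Asp, the label's name for the compound (L-Asp is the usual code for the amino acid L-aspartic acid), during the heat. The labels list 0.5, 1.0 and 1.5 mmol/L without saying which concentration was sequenced. Each group had 3 libraries, and the labels give 25 oocytes per group without saying how they were shared among the libraries. Total counts per library were 54965064 to 58361475 in control, 46198885 to 53327419 in heat stress and 41693395 to 49008681 in heat stress plus L-Asp.

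The 3 control libraries differed by little more than the sampling of fragments would give. In the control libraries low counts piled up at 4, 8 and 12 (604 genes at 4 counts in control replicate 1, against 330 at 3 and 216 at 5), so that 1 fragment added about 4 counts there. The heated libraries each had a pile at 4 counts, but not all had one at 8 or 12. Taking 4 counts per fragment, a gene with no count could still have had up to 0.206 to 0.288 CPM (counts scaled to a common library total), the level of 3 fragments, for counting error only, and in the heated libraries that number of counts is an assumption. Between pairs of control libraries the median index of dispersion, the squared difference relative to what independent single counts would give, was 5.19 to 5.22. It was 109 to 119 between heat stress libraries and 79.4 to 84.9 between L-Asp libraries. Among genes with 10000 to 30000 counts summed over the pair it was 5.57 to 6.42 in control and 309 to 658 in heat stress. The 3 control libraries were therefore averaged and counted as 1 sample, and 7 libraries entered every test: 1 control, 3 heat stress and 3 heat stress plus L-Asp. The lone control was assumed to vary as much as the other groups, and that spread could not be measured. In comparisons with control, few small p-values therefore do not show that RNA was unchanged. The labels do not say whether libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries.

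**Figure D1:**
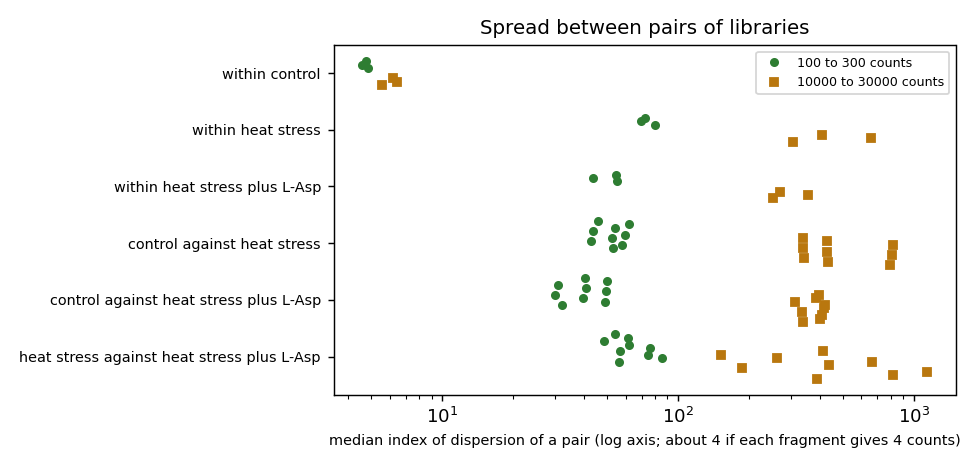
Each point is 1 pair of libraries, placed on a log axis by its median index of dispersion, with 1 row per kind of pair. Genes had 100 to 300 counts (circles) or 10000 to 30000 counts (squares) summed over the pair. The 3 control pairs lie between 4.56 and 6.42, and every other pair lies above 30.

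Heat stress against control asks what heat in the first part of maturation did to the RNA of MII oocytes. The clearest difference was in the genes of the cytosolic ribosome, the complex that translates mRNA. All 67 tested ribosomal protein genes had a fold change above 0 and the list rose, with a median log2 fold change of 1.21 (camera, adjusted p = 2.01e-39). With an estimated correlation the list's adjusted p was 0.418. Adjusted over the list alone, 36 of the 67 genes passed, against 0 adjusted over all genes tested. RPL27 measured 32.6 CPM in control and 112 ± 14.1 CPM (SD, n = 3) after heat stress, and RPL11 measured 35.9 and 120.0 ± 13.2 CPM. Ribosomal protein genes have many near-identical pseudogene copies that can share reads. Markers of cumulus and granulosa cells, the somatic cells that surround the oocyte, moved with this list, as given next.

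The cumulus and granulosa marker list rose as well (camera, adjusted p = 1.86e-05, and adjusted p = 0.418 with an estimated correlation). Of its 25 tested genes, 18 lay above 0, 13 were higher than control in each of the 3 heat stress libraries, and 0 passed when adjusted over the list alone. Its median log2 fold change was 0.36. The mean of 1.901 includes GATA6 and INHBA, at 0 CPM in control, whose fitted fold changes have no firm size. On log2 CPM with the prior count, the list mean was 1.477 in control and 2.582 ± 0.237 (SD, n = 3) after heat stress. A part of the list thus carried the difference. CYP11A1, which starts steroid synthesis in granulosa cells, measured 0.039 CPM in control and 9.16 ± 5.18 CPM (SD, n = 3) after heat stress. GJA1, the gap junction protein between granulosa cells, measured 0.80 and 9.16 ± 3.64 CPM. The most abundant markers on the list, which control libraries held as well, were RGS2 (942 and 1076 ± 235 CPM) and VCAN (133 and 167 ± 25.8 CPM). Theca and stroma markers mostly lay below 0 (1 of 9 tested genes above 0, median log2 fold change -0.31). So did blood and immune markers (2 of 6 above 0, median -0.682). Camera called neither list, which on so few genes does not show that they were unchanged. The endothelial list had fewer than 5 tested genes.

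Nuclear genes of the mitochondrial respiratory chain rose in the same comparison, with 50 of 68 above 0 and a median log2 fold change of 0.52 (camera, adjusted p = 4.35e-07, and adjusted p = 0.425 with an estimated correlation). COX6B1, a subunit of cytochrome c oxidase, measured 25.3 CPM in control and 78.1 ± 26.3 CPM (SD, n = 3) after heat stress. SDHD, a membrane subunit of succinate dehydrogenase, lay the other way at 42.1 and 14.5 ± 1.77 CPM. Glycolysis genes (14 of 20 above 0) and translation factors (25 of 37 above 0) passed narrowly (camera, adjusted p = 0.0489 each, and adjusted p = 0.582 and 0.418 with an estimated correlation). ALDOA measured 0.507 and 7.95 ± 3.39 CPM, ENO1 3.18 and 13.9 ± 5.65 CPM, and the elongation factor subunit EEF1B2 36.6 and 78.7 ± 6.32 CPM. For these 3 lists too, 0 genes passed when adjusted over the list alone. A contribution of cumulus cell RNA to them was not tested.

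The 13 genes encoded in mitochondrial DNA fell as a list (0 of 13 above 0, median log2 fold change -0.81, camera, adjusted p = 0.0489, and adjusted p = 0.748 with an estimated correlation). ATP6 measured 16647 CPM in control and 6807 ± 6763 CPM (SD, n = 3) after heat stress. The share of all counts from the mitochondrial genome was 10.0% to 10.1% in control and 3.09%, 5.18% and 14.5% in the 3 heat stress libraries, so that heat stress replicate 3 lay above control. Without heat stress replicate 1 the adjusted p was 0.448, without replicate 2 it was 0.264, and without replicate 3 it was 1.18e-08. It was also lost without control replicate 1 or 2 (0.0549 and 0.0545) and without L-Asp replicate 1, 2 or 3 (0.0863, 0.115 and 0.102). The glycolysis call was lost without control replicate 1 or 2 (0.0549 and 0.0545), heat stress replicate 2 or 3 (0.225 and 0.193) or L-Asp replicate 1 or 3 (0.0813 and 0.0618). The call of the translation factors was lost without control replicate 1 or 2 (0.0616 and 0.0559), heat stress replicate 1 or 2 (0.238 and 0.135) or L-Asp replicate 1, 2 or 3 (0.0543, 0.0773 and 0.0618). With a mean count of at least 50 or with the filter recomputed on 7 libraries, glycolysis (0.0629 and 0.0659) and the translation factors (0.0765 and 0.0967) did not pass either, and glycolysis did not pass in the fit of 9 libraries (0.0571).

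Among single genes, those of smallest p on the higher side included GSTA1, RPL27, RPL11 and TMSB10. GSTA1, a glutathione transferase (ENSSSCG00000052947, chromosome 7, 46538032 to 46548670), measured 15.8 CPM in control and 139 ± 32.2 CPM (SD, n = 3) after heat stress, a log2 fold change of 3.14 ± 0.50 (SE). TMSB10, an actin-binding thymosin (ENSSSCG00000008245, chromosome 3, 59776236 to 59777252), measured 17.4 and 122 ± 54.3 CPM. On the lower side, the polyubiquitin gene UBB (ENSSSCG00000018033, chromosome 12, 59171289 to 59172841) measured 16331 CPM in control and 4903 ± 553 CPM after heat stress, a log2 fold change of -1.74 ± 0.25 (SE). ID3, an inhibitor of helix-loop-helix transcription factors, measured 8183 and 2837 ± 317 CPM. POP5, TSPAN3 and PRELID3A measured 186, 688 and 202 CPM in control, and 53.4 ± 11.3, 219 ± 40.4 and 55.4 ± 8.28 CPM after heat stress. The build behind these coordinates is not given in the sources used here. UBB consists of near-identical ubiquitin repeats, and GSTA1 belongs to a family of similar genes, so their counts can hold reads of their relatives. For none of these single genes was it tested whether RNA of cumulus cells contributed.

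**Figure D2:**
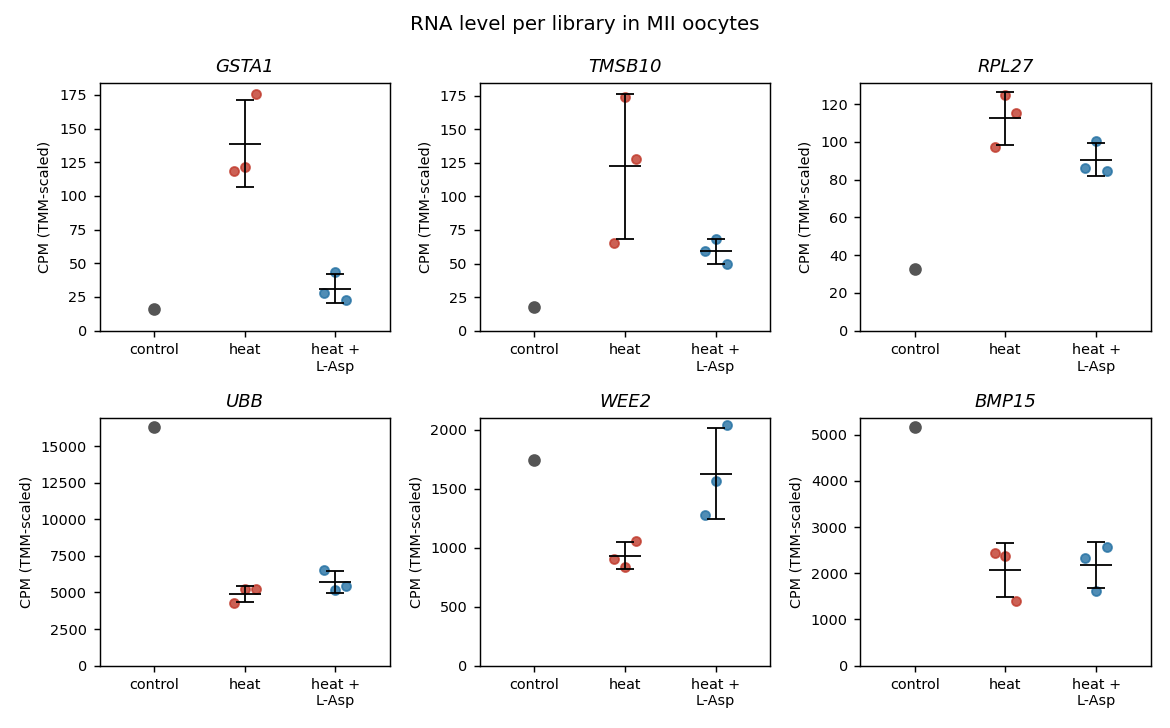
RNA level in CPM, scaled by trimmed mean of M values (TMM), of 6 genes in each library: 1 averaged control, 3 heat stress and 3 heat stress plus L-Asp libraries, with the group mean and SD as bars. GSTA1 was 118.8 to 176 CPM in the heat stress libraries, 22.57 to 43.55 CPM with L-Asp and 15.8 CPM in control.

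Heat shock and chaperone genes did not shift as a list (28 of 45 above 0, camera, adjusted p = 0.42). Adjusted over the list alone 2 members passed, both with lower RNA, among them UBB. Genes of the unfolded protein response went both ways, with ATF4 at 47.8 and 91.5 ± 12.5 CPM and the chaperone HYOU1 at 118 and 59.2 ± 25.4 CPM (SD, n = 3). Among antioxidant genes, GSTM3 measured 118 and 235 ± 18.2 CPM and PRDX2 702 and 412 ± 69.7 CPM. In the list of aspartate use and the malate-aspartate shuttle, asparagine synthetase ASNS measured 141 and 278 ± 31.96 CPM and MDH2 47.3 and 24.4 ± 1.901 CPM. Oocyte genes (11 of 36 above 0) and genes of meiotic arrest and resumption (15 of 49 above 0) did not pass (camera, adjusted p = 0.225 and 0.181). In them, the growth factor BMP15 measured 5174 and 2068 ± 584 CPM, TCL1A 25.5 and 7.89 ± 1.38 CPM, the kinase MOS 1537 and 643 ± 126 CPM, and UBE2C 531 and 232 ± 80.6 CPM. Of the regulators of maternal mRNA, BTG4 measured 15798 and 7322 ± 1688 CPM and CNOT11 111 and 230 ± 19.6 CPM.

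The remaining lists did not pass for heat stress against control (camera). Adjusted p-values were 0.0933 for chaperonins, 0.858 for the unfolded protein response, 0.225 for antioxidants, 0.757 for mitochondrial dynamics, 0.757 for aspartate use, 0.439 for nucleotide synthesis, 0.858 for the tricarboxylic acid cycle and 0.757 for lipids. They were 0.183 for apoptosis, 0.67 for autophagy, 0.433 for the proteasome, 0.757 for the spindle checkpoint, 0.487 for spindle microtubules, 0.487 for the actin cortex, 0.567 for cohesin and 0.849 for maternal mRNA control. DNA repair had 0.87, the mitochondrial ribosome 0.154, secretory traffic 0.42, DNA methylation and chromatin 0.757, inflammation and stress kinases 0.849 and splicing 0.181. The median was below 0 and the mean above 0 for maternal mRNA control, DNA methylation and chromatin, and inflammation. In mitochondrial dynamics 1 member, PHB2 (28.9 and 116 ± 33.0 CPM), passed when adjusted over the list alone.

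By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 15012 genes passed for heat stress against control, and the smallest adjusted p was 0.249. At an unadjusted p under 0.05 there were 579 genes (294 higher, 285 lower), where 751 would be expected by chance. DESeq2 on the same 7 libraries, with its own independent filtering of 22184 genes, called 172 genes (138 higher, 34 lower). The design planned at first, with the 3 control libraries as 3 replicates, called 433 genes (264 higher, 169 lower). In 10 simulations without any change, in which 1 control preparation was sampled 3 times, that design called 659 to 829 genes and the fit of 7 libraries at most 4.

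Heat stress plus L-Asp against heat stress asks what the added compound did. The ribosomal protein list was lower with L-Asp: 55 of 67 genes lay below 0, with a median log2 fold change of -0.30 (camera, adjusted p = 4.91e-05, and adjusted p = 0.747 with an estimated correlation). RPS3A measured 54.4 ± 13.6 CPM after heat stress and 19.7 ± 6.19 CPM with L-Asp (SD, n = 3 each), and RPS23 measured 34.3 ± 8.81 and 15.1 ± 1.25 CPM. None of the 67 genes passed when adjusted over the list alone. The call depended on heat stress replicate 2, the library with the highest mean of this list, and its adjusted p was 0.213 without it, against 6.7e-10 to 0.0195 without any other single library. Cumulus and granulosa markers were lower with L-Asp in 17 of 25 genes by fold change and did not pass (camera, adjusted p = 0.299).

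The gene of smallest p was GSTA1, at 139 ± 32.2 CPM after heat stress and 31.3 ± 10.9 CPM with L-Asp (SD, n = 3 each). Its log2 fold change was -2.15 ± 0.30 (SE), with an adjusted p of 0.134 by edgeR and 7.2e-09 by DESeq2. Whether this RNA came from the oocytes or from cumulus cells was not tested. The next on the lower side were RPS3A, the nuclear export factor CSE1L (26.4 ± 1.897 and 10.6 ± 1.54 CPM), the RNA-binding protein KHDRBS1 (117 ± 26.0 and 61.3 ± 3.75 CPM) and PAIP2 (12.4 ± 0.88 and 4.07 ± 0.62 CPM). On the higher side, KYAT1, which makes kynurenic acid, measured 17.97 ± 0.57 CPM after heat stress and 42.8 ± 9.15 CPM with L-Asp. LINGO2 measured 6.79 ± 2.95 and 20.9 ± 1.14 CPM, and RNF145 63.9 ± 20.1 and 133 ± 10.5 CPM. SUSD6 measured 50.4 ± 8.19 and 101 ± 21.4 CPM, and the mitochondrial carrier SLC25A44 48.2 ± 3.92 and 99.9 ± 32.7 CPM.

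Genes of meiotic arrest and resumption lay above 0 in 36 of 49 cases without passing (camera, adjusted p = 0.189). The oocyte kinase WEE2, which holds cyclin-dependent kinase 1 inactive, measured 932 ± 116 CPM after heat stress and 1627 ± 386 CPM with L-Asp (SD, n = 3 each), against 1745 CPM in control. PLK1 measured 47.3 ± 20.3 and 90.7 ± 30.6 CPM, and the oocyte importin KPNA7 3091 ± 819 and 5427 ± 1408 CPM. The deadenylase subunit CNOT11 measured 230 ± 19.6 and 141 ± 9.57 CPM. Mitochondrially encoded genes lay above 0 in 10 of 13 cases (adjusted p = 0.189), with ND4 at 3047 ± 2816 and 4908 ± 1754 CPM. In the list of aspartate use, the asparaginase ASRGL1 measured 11.8 ± 7.44 and 3.35 ± 0.32 CPM and the amino acid transporter SLC1A5 513 ± 206 and 967 ± 440 CPM, with 12 of 26 members above 0 (camera, adjusted p = 0.556). Heat shock genes (19 of 45 above 0), antioxidant genes (12 of 44) and apoptosis genes (14 of 30) did not pass (camera, adjusted p = 0.521, 0.189 and 0.674). Every list but that of the cytosolic ribosome had an adjusted p of 0.189 or more. The median of the aspartate list was below 0 and its mean above 0. HSPH1 measured 288 ± 84.5 and 188 ± 45.0 CPM, and PGD 41.1 ± 10.5 and 74.3 ± 22.3 CPM.

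By edgeR 0 of 15012 genes passed for heat stress plus L-Asp against heat stress (smallest adjusted p 0.134), with 993 genes at an unadjusted p under 0.05 where 751 would be expected. DESeq2 called 183 genes (78 higher, 105 lower), and edgeR on all 9 libraries called 2, GSTA1 lower and the unnamed gene ENSSSCG00000052153 higher, the latter named here after its values were seen (2.79 CPM in control, 0 in all 3 heat stress libraries and 5.52 ± 3.19 CPM with L-Asp). CPM values of the 2 groups did not overlap for 1779 genes, 11.9% of those tested, where chance gives 10%.

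Heat stress plus L-Asp against control asks what still differed from unheated oocytes. Ribosomal protein genes rose here too, with 63 of 67 above 0 and a median log2 fold change of 0.89 (camera, adjusted p = 1.13e-28, and adjusted p = 0.726 with an estimated correlation), and 11 passed when adjusted over the list alone. RPL11 measured 35.9 CPM in control and 97.6 ± 9.30 CPM with L-Asp (SD, n = 3), and RPL27 32.6 and 90.5 ± 8.72 CPM. Nuclear respiratory chain genes rose in the same way (51 of 68 above 0, camera, adjusted p = 5.73e-05, and adjusted p = 0.804 with an estimated correlation), with COX7B at 105 and 235 ± 24.2 CPM and COX6C at 120 and 248 ± 24.6 CPM. Cumulus and granulosa markers rose with them (17 of 25 above 0, camera, adjusted p = 0.00202, and adjusted p = 0.726 with an estimated correlation). CYP11A1 measured 3.27 ± 3.94 CPM with L-Asp. The other lists had adjusted p-values of 0.105 or more, with 17 of 26 genes of the aspartate list above 0 (0.586).

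The genes of smallest p on the higher side were PHB2, HAX1, RPL11, UQCC5 and RPL27. Prohibitin PHB2, of the mitochondrial inner membrane, measured 28.9 CPM in control and 125 ± 25.9 CPM with L-Asp (SD, n = 3), and HAX1 120 and 341 ± 60.2 CPM. On the lower side POP5 measured 186 and 39.2 ± 2.17 CPM, UBB 16331 and 5724 ± 731 CPM, FSTL4 75.8 and 19.2 ± 4.71 CPM, and UBE2T 130 and 33.8 ± 12.6 CPM. BMP15 measured 2174 ± 495 CPM and BTG4 7384 ± 2128 CPM with L-Asp, close to their heat stress means of 2068 and 7322 CPM. By edgeR 0 of 15012 genes passed (smallest adjusted p 0.18), with 484 genes at an unadjusted p under 0.05. DESeq2 called 64 genes (43 higher, 21 lower) and edgeR on all 9 libraries 269 (174 higher, 95 lower).

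**Figure D3:**
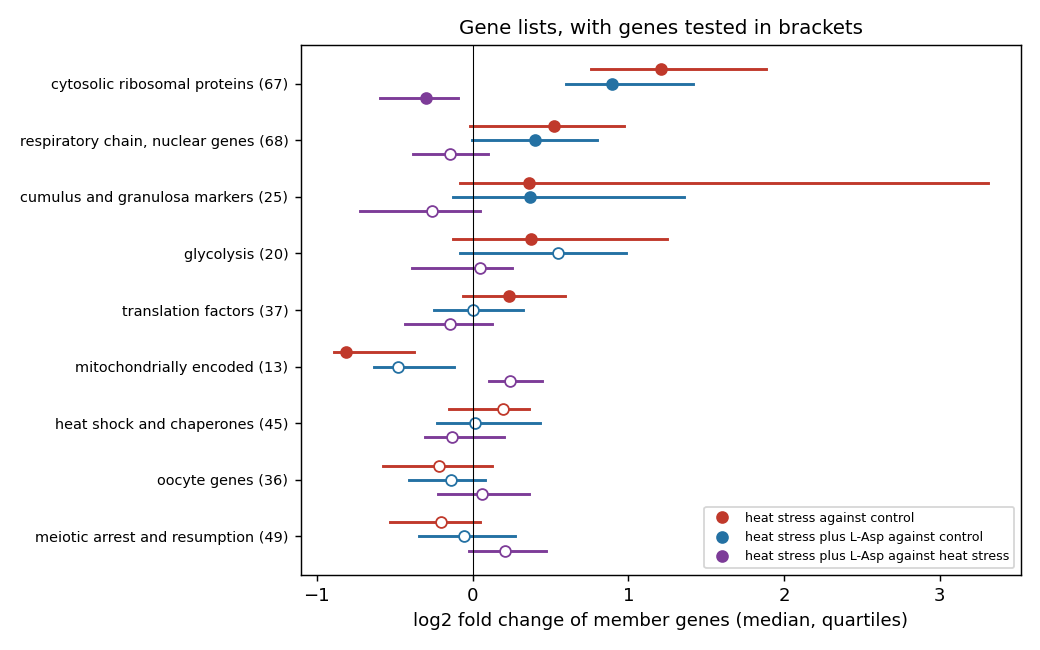
Median (point) and quartiles (line) of the log2 fold change over the tested genes of 9 lists in the 3 comparisons, with the number of tested genes in brackets. Filled points mark lists with an adjusted p under 0.05 by camera with its preset correlation, calls that were lost with an estimated correlation, and the ribosomal protein list lay highest against control at 1.21 and 0.89.

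A single test for any difference among the 3 groups called 0 genes by edgeR (smallest adjusted p 0.126, 672 genes at an unadjusted p under 0.05), 88 by the likelihood ratio test of DESeq2 and 345 by edgeR on all 9 libraries. In the main fit of edgeR no gene was called for heat stress and called in the opposite direction for L-Asp, and 42 were by DESeq2. Without a filter edgeR called GSTA1 (higher after heat, lower with L-Asp) and ENSSSCG00000052153 (lower, then higher). Across genes, which are not independent replicates, the heat effect and the L-Asp effect had a correlation of -0.55. Unchanged groups simulated with the same shared heat stress libraries gave -0.35 (range -0.37 to -0.33). The covariance was -0.73 against a simulated -0.49. With the heat effect taken from 1 heat stress library and the L-Asp effect from the other 2, the correlations were -0.11, -0.10 and -0.06 and the covariances -0.22, -0.19 and -0.11. For the heat effect and heat stress plus L-Asp against control, which share the control, the observed correlation of 0.58 lay below the simulated 0.75 (range 0.74 to 0.76), and the covariance of 0.79 below 1.46. The simulation thus overshot in that pair, and its values are no firm measure of chance in the other, where part of the excess may come from the shared libraries.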

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

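Counts of called genes under edgeR stayed at 0 in all 4 gene tests with RLE size factors, with scaling that leaves out mitochondrially encoded and abundant genes, with a mean count of at least 50 and, where it applies, with a log2 fold change of at least 1. Other settings gave calls, and unless stated the cause was not tested. For heat stress against control, heat stress plus L-Asp against heat stress, heat stress plus L-Asp against control and the 3 groups together, the fit without a filter called 9, 2, 3 and 7 genes. GSTA1 was among these in all but the third, where POP5 and UBB were among those that passed. DESeq2 called 172, 183, 64 and 88 genes, and the fit of 9 libraries as planned 433, 2, 269 and 345. In simulations without change that fit gave 659 to 829 calls for heat stress against control, so its count does not separate heat from the repeated control. The filter recomputed on 7 libraries, chosen after seeing the data as was the fit of 7 libraries, called 2 genes for L-Asp against heat stress (GSTA1 and ENSSSCG00000052153) and 5 among the 3 groups. With only the 2 groups compared, 1 gene passed for heat stress plus L-Asp against control (ENSSSCG00000047655).

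Leaving out 1 library at a time gave 0 to 1 genes for heat stress against control, 0 to 3 for L-Asp against heat stress, 0 to 1 for L-Asp against control and 0 to 1 among the groups. The calls were ENSSSCG00000047655, GOLPH3L and ENSSSCG00000042401 without heat stress replicate 1, and ZSWIM7, MTPN and ENSSSCG00000047003 without heat stress replicate 3. They were ENSSSCG00000055543 without L-Asp replicate 1 and MRPL43 without L-Asp replicate 2, all named after their values were seen. Leaving out a single library moved the list counts to 3 to 6 of 6 for heat stress, 0 to 3 for L-Asp against heat stress, where the main count was 1, and 3 to 4 for L-Asp against control. Calls of the ribosomal, respiratory chain and cumulus lists against control held in 9 of 9 such fits. Those of glycolysis, translation factors and mitochondrially encoded genes held in 3, 2 and 2. Fits without 1 control library kept the other, nearly identical control libraries, so they say little about dependence on the control. The control as a whole was never left out.

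The replicate numbers did not pair the libraries: deviations of same-numbered heat stress and L-Asp libraries correlated at 0.052, -0.021 and 0.010, and not every library correlated best with its own number. The replicate block called 1 gene for heat stress against control, 1 for L-Asp against control and 1 among the groups, each time ENSSSCG00000047655, and 2 lists for L-Asp against heat stress. The glycolysis list did not pass with the block for heat stress against control (adjusted p = 0.0533).

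With an estimated correlation, 0 lists passed in each comparison and 0 of the marker lists. With fry, 0 passed for heat stress and for L-Asp against control, and 0 of the marker lists. For L-Asp against heat stress fry called 1 list, mitochondrial dynamics (adjusted p = 0.00201, higher), in place of the ribosomal list (0.602). Opposite calls for heat and L-Asp numbered 42 with DESeq2, 2 with 9 libraries and 0 to 1 with 1 library left out. Without a filter GSTA1 and ENSSSCG00000052153 were such calls, so the count of 0 depended on the filter. Of 223 pairs of gene and comparison that the naming rule gave, 11 passed without a filter, 55 with DESeq2, 86 with 9 libraries, 1 with the recomputed filter and 0 to 2 with 1 library left out. Enriched terms, which had no calls to run on here with either background, numbered 51 with 9 libraries. None of the 70 genes taken from the naming rule and no called list changed direction under any setting run. These genes and lists were chosen from the same libraries that the settings refit. A kept direction was thus likely beforehand and says little about other libraries. At this depth and replication the fit could rarely detect a 2-fold change in single genes (1.6% recovered in simulation for heat stress against control).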

Other observations

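All tests in this part were chosen after the data were seen, except the slope test of the ribosomal rise and the splits of the heated libraries. Camera over 2739 GO and KEGG terms in the fit of 7 libraries called 19 terms higher and 2 lower for heat stress against control, 0 and 3 for L-Asp against heat stress, and 12 and 3 for L-Asp against control. None of them passed with an estimated correlation. Most of those higher after heat stress were ribosome and translation terms. Of the 50 genes of the term structural constituent of chromatin, 42 lay above 0 after heat stress (median log2 fold change 0.81, adjusted p = 0.00225, and adjusted p = 0.999 with an estimated correlation). Most genes of the term were low, with a median of 0.858 CPM in control and 1.83 CPM after heat stress. The histone variant gene H3-3A measured 231 CPM in control, 347 ± 48.6 CPM after heat stress and 232 ± 27.4 CPM with L-Asp, whereas the oocyte linker histone H1-8 measured 4193, 2823 ± 462 and 3862 ± 365 CPM (SD, n = 3). Other abundant members that lay lower after heat stress were ENSSSCG00000017202 (2501 and 1787 ± 413 CPM) and H2AZ1 (230 and 185 ± 30.0 CPM). H2AZ2 (46.1 and 39.1 ± 4.33 CPM) and H2BK1 (22.9 and 5.25 ± 3.19 CPM), the member of smallest p, lay lower too. CENPA (56.6 and 63.2 ± 9.955 CPM) and H2AC4 (19.5 and 33.9 ± 6.37 CPM) lay higher. The rise of the term thus rested mostly on genes of low level. These genes were picked after their values were seen. The filter took the control libraries as 3 samples, so a gene detected only in control could pass it. In the term olfactory receptor activity OR10A4 did so, at 0.663 CPM in control and 0 in both heated groups. A lower level of that term may thus come in part from the filter, which was not tested. Genes of the term olfactory receptor activity were lower (20 of 65 above 0, adjusted p = 0.0056, and adjusted p = 0.999 with an estimated correlation), at medians of 0.722 CPM in control and 0.493 CPM after heat stress.

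Polyadenylated RNA of ribosomal protein genes was higher in each of the 6 heated libraries than in control, with list means of 4.84 to 5.603 log2 CPM against 4.003. Transcript length is argued against. The median log2 fold change of 1.21 lay at percentile 100 of 10000 random lists matched on length and level, whose highest median was 0.62. RNA carried over from cumulus cells may have contributed, since the oocytes matured inside cumulus cells and some marker genes rose. The mean levels of CYP11A1, GJA1 and, picked after its values were seen, VIM (0.137 CPM in control, 3.32 ± 1.94 CPM after heat stress) lay above control. Of the 25 marker genes, 12 were under 1 CPM in control. Several of these stayed under 1 CPM after heat stress, among them PTGS2 (0.741 and 0.656 ± 0.781 CPM) and CYP19A1 (0.644 and 0.584 ± 0.121 CPM). By fold change 18 of the 25 genes lay above 0 and 7 below. If carried-over RNA added a like amount to each gene, the slope of the log2 rise on the log2 control level would be near 0. For a multiplied level it would be near 1. For heat stress, with all 67 genes above control, the slope was 0.522 ± 0.062 (SE). That is within 2 SE of the mark of 0.5 set for the test, which decides neither. Over the genes above control, and so chosen by the outcome, the slope was 0.580, 0.523 and 0.681 in heat stress replicates 1 to 3 (57, 67 and 65 genes). With L-Asp it was 0.687 ± 0.071 (63 genes, and 0.646, 0.701 and 0.687 by library). It lay above the mark by more than 2 SE in heat stress replicate 3 and the L-Asp libraries but not in heat stress replicates 1 and 2. The amount that carried-over RNA would add to each gene was not measured, and the control level enters both sides of the slope. The slope thus cannot decide, and cumulus RNA stays open. The control was 1 preparation at rank 1 of 7, so a difference of that preparation and an effect of heat, which was not tested apart from it, cannot be told apart.

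The near identity of the 3 control libraries is the other pattern weighed. Greater depth is argued against, since at equal counts of 100 to 300 the lowest index within the other groups was 43.8 and the highest in control 4.82. The control index rose by a factor of 1.41 at most from the lower to the higher abundance class, where the other groups rose by at least 3.85, which is consistent with 1 preparation sequenced 3 times. Control libraries also had more genes with a count (17433 to 17685) than the heated libraries (14730 to 15808), and no biological explanation was tested.

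For L-Asp against heat stress the 6 libraries make 10 splits, too few for a share under 0.05. The real split called 0 genes and the highest of the others 2, and a count of 0 is reached by all 10 splits by construction. At an unadjusted p under 0.05 the real split had 993 genes and the others 288 to 1618. It called 1 list and the highest of the others 4, and 7 of 10 splits gave as many lists.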
